A study of Mus musculus with 4 samples.

How the data were processed

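Gene expression was measured in alveolar type II cells, the surfactant-making epithelial cells of the lung alveolus, sorted by flow cytometry from mouse lungs. Per the labels, wild-type (WT) and Tlr3-deficient mice either received Lewis lung carcinoma cells under the skin or did not, and lungs were taken 2 weeks later. There are 4 groups (WT without tumor, WT with tumor, Tlr3-deficient without tumor, Tlr3-deficient with tumor) with 1 array per group, so no difference has a replicate check and no p-value is given. The number of arrays limits the precision of every value. The labels do not say how many mice were pooled into an array.

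Each array holds 1 colour, Cy3, on the Agilent mouse design 014868. Spot intensity was extracted with Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. The deposited processed signal is a linear intensity, background-subtracted and detrended within each array by that program, with small surrogate values in place of signals too low to measure, per the file headers. It had not been scaled between arrays. The series' own value table holds log2 values that the authors deposited for the same arrays, and how it was made is not given in the sources used here. Set against the scanner files, its 4 columns correlated with log2 processed signal at r = 0.9995, 0.9995, 0.9998 and 0.9995 across probes in the order WT without tumor, WT with tumor, Tlr3-deficient without tumor and Tlr3-deficient with tumor. The columns had medians of 6.312, 6.313, 6.312 and 6.312, their sorted values were nearly identical, and genes were not centred, so it behaves as a log2, quantile-normalized table in the scanners' direction. It departs from the scanner files at 6 probes of 4 genes (Tlr3, Cxcl1, Cxcl2 and Cxcl12), where the 2 sources give different values. The scanner files are used for every main value, and the table only as an alternative.

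The main values are log2 processed signal minus each array's 75th percentile over probes other than controls. Spots with an outlier flag were left out, spots of 1 probe were averaged, and a gene was represented by its probe with the highest mean over the 4 arrays. The mean of all probes was an alternative. Of 41174 gene probes, 27668 were named through their RefSeq accession in a table of the GRCm38 assembly used for names alone, and the rest kept the name in the scanner files, which can be old. In all, 33716 probes carried a gene symbol of that table and the probes made 27340 gene names. Coordinates are those of the array annotation, on mm9. A gene counted as well above background on an array if Feature Extraction flagged any of its probes so. This flag came from a probe other than the one representing the gene for 35, 17, 22 and 15 genes on the arrays in the order above, and the 4 ranked genes among these are given with both probes. There were 15676 such genes on all 4 arrays and 18696 on at least 1.

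A gene was tested in a comparison when it was well above background on at least 1 of the 2 arrays, and was called when it differed by at least 2-fold. Where it was well above background on only 1 of them, the difference is a bound, written "at least N-fold": the brighter value against the higher of the dim probe's own value and the lowest signal among probes well above background on that array. The bounds belong to this background correction. The normexp alternative adds an offset of 50 to each corrected intensity, where the arrays' median processed intensities were 57.6 to 100. The offset shrinks log2 differences of dim genes by construction, so smaller values with normexp are no independent check of size. With normexp, all 40 of the largest bounds named kept their direction and at least a 2-fold difference. The difference was smaller than the bound in 40 of 40. They also belong to the brightest probe: with the mean of all probes the difference was smaller than the bound in 11 of 40, and 1 fell under 2-fold. Of 152 differences of ranked genes and Tlr3, 114 moved by over 1.5-fold with normexp and 27 with the mean of all probes. Log2 differences of such genes are measured values and are named as such or given with the bound. The counts and ranked genes for the difference of tumor changes between genotypes were taken over genes well above background on all 4 arrays. Its list medians used members well above background on at least 1 of the 4 arrays, at measured values without bounds. Precision within an array comes from replicate spots and from the scanner's error model. The standard deviation (SD) of the log2 difference between replicate spots was 0.287 for WT with against without tumor, 0.109 for Tlr3-deficient with against without tumor, 0.293 between genotypes without tumor and 0.110 between genotypes with tumor. These values cover spots, not animals.

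For 40 gene lists (cell type markers, innate immune, stress, metabolic and check lists) the median log2 difference of the measured members was set against 10000 random lists of the same size matched on signal. A list is said to stand apart when its percentile is under 2.5 or over 97.5, which chance gives for 2 of 40 lists. This describes these arrays and is not a test of the conditions. The genes named are Tlr3; the 10 largest measured differences each way in both tumor comparisons and between genotypes with tumor, and 5 each way between genotypes without tumor; the 8 largest differences of tumor changes each way; the 10 largest changes each way shared by both genotypes; up to 5 largest bounds each way; the 4 members of a list with the largest difference; and every measured neutrophil attractant. Genes ranked by measured difference needed their probes well above background on both arrays to go the same way as each other, which the representing probe need not be, as for Lypd6 and Racgap1. Ranked genes needed a symbol that is no clone, accession or predicted-gene name, so unnamed probes with larger differences are not ranked. Genes named outside that rule are said to be so. The comparisons, lists, rules and 9 alternatives were fixed before the data were examined. The alternatives were normexp background correction, 3 other scalings (quantile, median, cyclic loess), the percentile over another set of probes, 2 filters on dim probes, the mean of all probes, and the series' value table. Slide as a block could not be fitted, since 1 array per group leaves no residual degrees of freedom. A split by array column, counts without chromosomes X and Y and counts with the flag of the representing probe alone were added after the data were seen, as were lists with every gene at its bound and the comparison of the value table with the scanner files probe by probe.

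The calling rule was tested on simulated arrays made from the real signals, with normally distributed noise of 1 replicate-spot SD per array. For WT with against without tumor (16907 genes), 41 of 50 genes simulated at 2.5-fold and 50 of 50 at 4-fold were called in the right direction, as was 1 of 50 at 1.5-fold, and 27 of 16707 unchanged genes were called. For Tlr3-deficient with against without tumor (17192 genes), the numbers were 48 of 50, 50 of 50, 0 of 50 and 0 of 16992. On the real WT array without tumor the noise was one-sided. Of 936 replicate spots in columns 1 to 51, 19 lay 2-fold below their probe's median and 1 above. The simulation holds no such scatter and no difference between animals or slides. Its number of unchanged genes called is therefore no error rate of the real comparisons. Of 200 simulated random lists of 12 genes, 5.5% stood apart, and of lists shifted by 0.5 log2 units 100% did. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.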

Results

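The study profiled alveolar type II cells from 4 groups of mice: WT and Tlr3-deficient, each without a tumor or 2 weeks after Lewis lung carcinoma cells, a mouse lung cancer line, were placed under the skin. Tlr3 encodes a receptor for double-stranded RNA. The design addresses which genes of these cells differ in tumor-bearing mice, and whether those differences depend on Tlr3. Each group is 1 array, so every difference below describes a pair of arrays. The 75th percentile of the processed intensity was 555 on the WT array without tumor, 796 on the WT array with tumor, 758 on the Tlr3-deficient array without tumor and 904 on the Tlr3-deficient array with tumor. The share of gene spots well above background was 61.0%, 65.5%, 63.3% and 65.0% in the same order, and no spot was saturated. The arrays came from 3 slides, with the WT tumor array and the Tlr3-deficient array without tumor on the same slide, so slide and group cannot be told apart for the tumor or genotype comparisons. The E1A spike-in control lay 1.68, 1.13, 1.14 and 0.21 log2 units over the 75th percentile in the same order. It fell in both tumor and both genotype comparisons, so slide cannot be told apart from what either pair shares.

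Tlr3 itself was dim on all arrays. Its brighter probe (mm9 chromosome 8, 46481729 to 46481788, minus strand) read -3.93 on the WT array without tumor and -3.94 with tumor, in log2 units relative to the array's 75th percentile, against -5.45 and -5.30 on the Tlr3-deficient arrays. Tlr3 was at least 2.44-fold lower in the Tlr3-deficient array without tumor, where it was not well above background, and 2.55-fold lower with tumor, where it was. With normexp these differences were -0.61 and -0.62 log2, under 2-fold in both. The tumor difference of this probe was -0.02 in WT, and the dimmer probe (46482009 to 46482068) differed by 0.73 with tumor in WT and by -1.26 between genotypes with tumor. Neither probe was well above background on the Tlr3-deficient array without tumor, so the tumor differences in Tlr3-deficient cells (0.15 and 1.01) and the dimmer probe's genotype difference without tumor (-1.54) are measured values against a dim spot. The labels do not say whether the probes lie in the deleted part of the gene, so these levels check the genotype labels only in part. The series' value table gives other values for Tlr3, a tumor difference of 7.44 in WT and a genotype difference of -8.25 with tumor, which the scanner files do not hold.

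Sex-linked genes separated 1 array from the others. All mice are labelled female. Xist, the RNA that silences an X chromosome in female cells, was lower in the array labelled Tlr3-deficient, no tumor, than in WT without tumor, by a log2 difference of -8.10 (-7.50 with the mean of its probes). Its antisense partner Tsix differed by -4.12. The Y-linked genes Eif2s3y and Ddx3y were at least 82.8-fold and at least 80.2-fold higher there, and Kdm5d was at least 15.8-fold and Uty at least 2.46-fold higher. Of the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, 4 were well above background on that array and 0 on each of the other 3. The sex-linked list had medians of -0.13 for tumor in WT, -4.92 for tumor in Tlr3-deficient cells (-4.15 with bounds), 5.88 between genotypes without tumor (3.98 with bounds) and -0.04 with tumor. With only genes well above background on all 4 arrays, which leaves Xist alone, the tumor difference in Tlr3-deficient cells turned to 7.85 and the genotype difference without tumor to -8.10. Every comparison that uses the array labelled Tlr3-deficient, no tumor, therefore also sets arrays with and without Y-linked transcripts against each other.

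**Figure D1:**
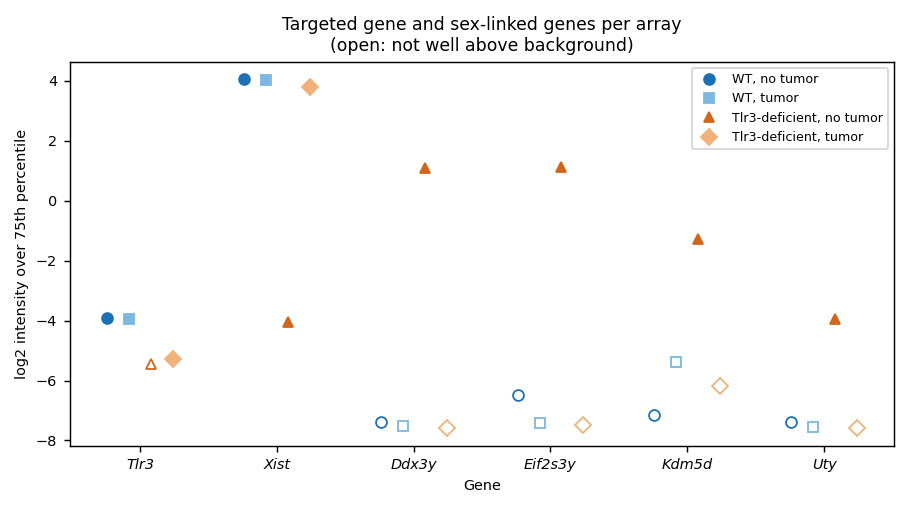
Log2 intensity relative to the array's 75th percentile (vertical axis) of Tlr3, Xist and 4 Y-linked genes (horizontal axis), 1 point per array, with open symbols where the gene was not well above background. The array labelled Tlr3-deficient, no tumor, has Xist at -4.05 against 3.80 to 4.05 on the others.

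In WT mice, neutrophil transcripts were higher with tumor. S100a8 and S100a9, which encode the subunits of calprotectin, were 41.9-fold and 36.1-fold higher, and Retnlg, a neutrophil resistin-like gene, was 25.4-fold higher. Wfdc17 (at least 63.1-fold), Clec4e (at least 31.8-fold), Il1r2 (at least 21.4-fold) Mefv (at least 13.8-fold) and the chemokine Cxcl5 (at least 13.3-fold) had the largest bounds among the ranked genes. Among their largest measured differences were also Ifitm6 (4.47 log2), Cd300lf (3.70), Pirb (3.52), Rbp7 (3.33), Coro1a (3.30), Clec4d (3.24) and Cd52 (3.23). Lower with tumor were Cd5l (-3.19), a macrophage-secreted protein, Cyp1a1 (-3.05), a target of the aryl hydrocarbon receptor, Cys1 (-2.89), the clock-controlled factor Dbp (-2.68), P2ry14 (-2.53), Ccdc62 (-2.40), Cyp2a22 (-2.16), Sphk1 (-2.14), Ciart (-2.14) and the clock repressor Nr1d1 (-1.88). H2bc22 was at least 8.91-fold lower, Spag6 7.62-fold, Vmn2r59 6.84-fold, Pcyt1b 6.73-fold and Polq 6.48-fold at the least by their brightest probes. With the mean of all probes Spag6 differed by -2.51, Polq by -2.23 and Pcyt1b by -0.97, each less than its bound.

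Of 12 measured neutrophil markers, 11 were at least 2-fold higher with tumor in WT, with a median of 4.09 (2.79 with 6 members at their bound), above the random lists. Csf3r, the receptor for granulocyte colony-stimulating factor, was at least 9.07-fold higher. Other markers of blood and immune cells differed less. Alveolar macrophage markers had a median of 0.18, T and NK cell markers 0.72 (0.70 with bounds; 0 of 10 called), B cell markers 0.86 and monocyte and dendritic cell markers 0.56 (0.42 with bounds), all within the range of random lists. With bounds in the random lists too, T and NK markers (percentile 98.14) and B cell markers (percentile 99.38) stood apart upward. Erythroid markers (1.30, or 0.94 with bounds; 3 of 8 higher) and platelet markers (1.10; 4 of 7 higher) stood apart, with Slc4a1, the red cell anion exchanger, 8.99-fold higher. The alveolar type II markers themselves had a median of -0.11 with 0 of 17 called.

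The genes that attract or feed neutrophils stood apart with a median of 0.66 in WT (percentile 99.65), with 2 of 7 at least 2-fold higher: Cxcl5, and Il1b at 7.90-fold. The measured log2 differences of the others were 0.97 for Cxcl2, 0.66 for Cxcl3, 0.57 for Csf2, 0.20 for Cxcl12 and 0.13 for Cxcl1. The series' value table instead gives WT tumor differences of 10.25 for Cxcl1, 7.24 for Cxcl12 and 3.89 for Cxcl2, and a list median of 3.60, so for these genes and Tlr3 the size of the WT tumor difference depends on which deposited source is read. Other chemokines and cytokines had a median of 0.62 (3 of 20 higher), among them Ccl8 (at least 6.31-fold), Ccl9 (2.59-fold) and Ccl20 (2.56-fold), while Tnf was at least 1.64-fold higher, under the threshold. Type I interferon-stimulated genes had a median of 0.30, with Rsad2 (7.60-fold) and Ddx60 (at least 2.34-fold) the 2 of 28 called. Interferon-gamma response genes had a median of 0.48 (5 of 15 higher), epithelial acute phase genes 0.26 (4 of 16 higher, Reg3g at 2.66), MHC class II genes 0.41 and pattern recognition receptors 0.19, each standing apart upward. So did 3 lists whose sign depended on the processing: MHC class I genes (0.17, but -0.09 with normexp), NF-kB targets (0.13, but -0.02 with median centring) and immediate early genes (0.05, but -0.10 with median centring).

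Lists that stood apart downward in WT with tumor were alveolar type I markers (-0.73; 3 of 11 lower), circadian clock genes (-0.79; 5 of 14 lower and 2 higher), heat shock genes (-0.53), glucocorticoid-induced genes (-0.51), endothelial markers (-0.42), club cell markers (-0.42), fibroblast and pericyte markers (-0.38) and genes of the unfolded protein response (-0.34). Ciliated cell markers were higher (0.59). In all, 1007 genes were at least 2-fold higher (427 as bounds) and 277 lower (108 as bounds) of 17711 tested, and 14 lists stood apart upward and 8 downward. Higher genes made up 78.4% of these calls, but 66.4% with quantile normalization and 63.7% with median centring. The counts were 460 and 126 with normexp and 2072 and 812 without a filter on dim probes. Replicate spots of the WT array without tumor scattered more in array columns 1 to 51 (SD 0.357) than in columns 52 to 85 (SD 0.142). Among genes with probes in columns 52 to 85, 3.40% were higher, against 7.27% in columns 1 to 51 and 5.69% of all genes tested.

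In Tlr3-deficient mice neutrophil transcripts were also higher with tumor. S100a8 was 28.8-fold (4.85 log2) and S100a9 20.3-fold (4.34) higher, with Ifitm6 (4.51 log2) and Wfdc17 (4.47) between them and Clec4e (4.07) below. Jchain, which joins antibody chains in plasma cells, was 165-fold higher, the largest measured difference of a ranked gene outside Xist, and the antibody light chain gene Iglv1 was 138-fold higher, ahead of Slc6a20a (3.86). The largest upward bounds of ranked genes were all those of antibody variable genes, Igkv3-4 (at least 85.5-fold), Igkv1-117 (67.8-fold), Igkv4-59 (59.2-fold), Igkv4-55 (58.4-fold) and Ighv1-77 (55.1-fold at the least). With normexp their measured log2 differences were 4.79, 4.54, 4.28, 4.35 and 3.94, and those of Clec4e, Il1r2, Mefv and Cxcl5 in WT 2.90, 2.55, 1.81 and 1.82, each less than the gene's bound. Lower were genes of elastic fibers and matrix, Eln (-3.28), Fbn2 (-3.05) and Mfap5 (-2.76), together with Arxes1 (-3.11), Veph1 (-2.99), Ecrg4 (-2.72), Evl (-2.70), Kntc1 (-2.66), Peg3 (-2.63) and Fras1 (-2.62), and Mirg and Zdhhc15 were at least 8.66-fold and 7.54-fold lower. With the mean of all probes Zdhhc15 differed by -1.37, less than its bound, and Cd300lf by 2.71 against 3.47 at its brightest probe. Xist, Tsix and the Y-linked genes also differed here, between the array labelled without tumor and the one with tumor.

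Of the neutrophil markers, 11 of 12 were again at least 2-fold higher (median 3.54, or 2.89 with 5 members at their bound), with Camp at least 8.14-fold higher. Here alveolar macrophage markers stood apart as well (median 1.51; 7 of 12 higher, Itgax 6.81-fold and Chil3 4.59-fold), as did T and NK cell markers (1.63, or 0.81 with bounds), B cell markers (1.29, or 0.66 with bounds) and monocyte and dendritic cell markers (0.80). MHC class I genes had a median of 1.10 with 6 of 11 higher, among them Tap1 (1.47) and Psmb9 (1.46), and MHC class II genes one of 0.64, led by H2-DMb2 (3.03). Erythroid and platelet markers were lower, at medians of -0.77 and -0.79. Type II markers had a median of 0.06 with 0 of 17 called.

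Neutrophil attractants had a median of 0.71 (3 of 7 higher): Il1b was 9.66-fold, Cxcl2 2.27-fold and Cxcl5 2.25-fold higher, while Cxcl3 (0.71), Csf2 (0.41), Cxcl1 (0.37) and Cxcl12 (-0.27) were under 2-fold. Other lists standing apart upward were acute phase genes (0.52; Pigr 8.29-fold higher), cholesterol synthesis (0.62; 1 of 16 called), NRF2 antioxidant genes (0.43), fatty acid and phospholipid synthesis (0.29), other chemokines (0.53, or 0.41 with bounds), interferon-gamma response genes (0.55), type I interferon-stimulated genes (0.19; 2 of 28 lower and none higher), pattern recognition receptors (0.28), NF-kB targets (0.29), immediate early genes (0.14) and ciliated markers (0.55). Downward stood type I markers (-1.08; 6 of 11 lower), fibroblast and pericyte markers (-0.50, Col3a1 at -2.32), glucocorticoid-induced genes (-0.69), transitional state genes (-0.48), cell cycle genes (-0.41), endothelial markers (-0.31), genes tied to the pre-metastatic niche (-0.28), heat shock genes (-0.23) and the unfolded protein response (-0.19). With bounds in the random lists too, 2 of these lists no longer stood apart: the niche genes, of which 6 were called higher, S100a8 and S100a9 among them, and 3 lower (median -0.08, random range -0.21 to 0.20), and the pattern recognition receptors (0.18, at the upper end of -0.20 to 0.18). There were 811 genes higher (319 as bounds) and 702 lower (285 as bounds) of 17860 tested, against 405 and 327 with normexp and 1443 and 1567 without a filter. Of genes with probes in columns 52 to 85, 2.52% were lower, against 3.93% of all and 4.86% in columns 1 to 51. This comparison does not use the noisier WT array, and replicate spots in columns 1 to 51 had SDs of 0.114 without and 0.079 with tumor.

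**Figure D2:**
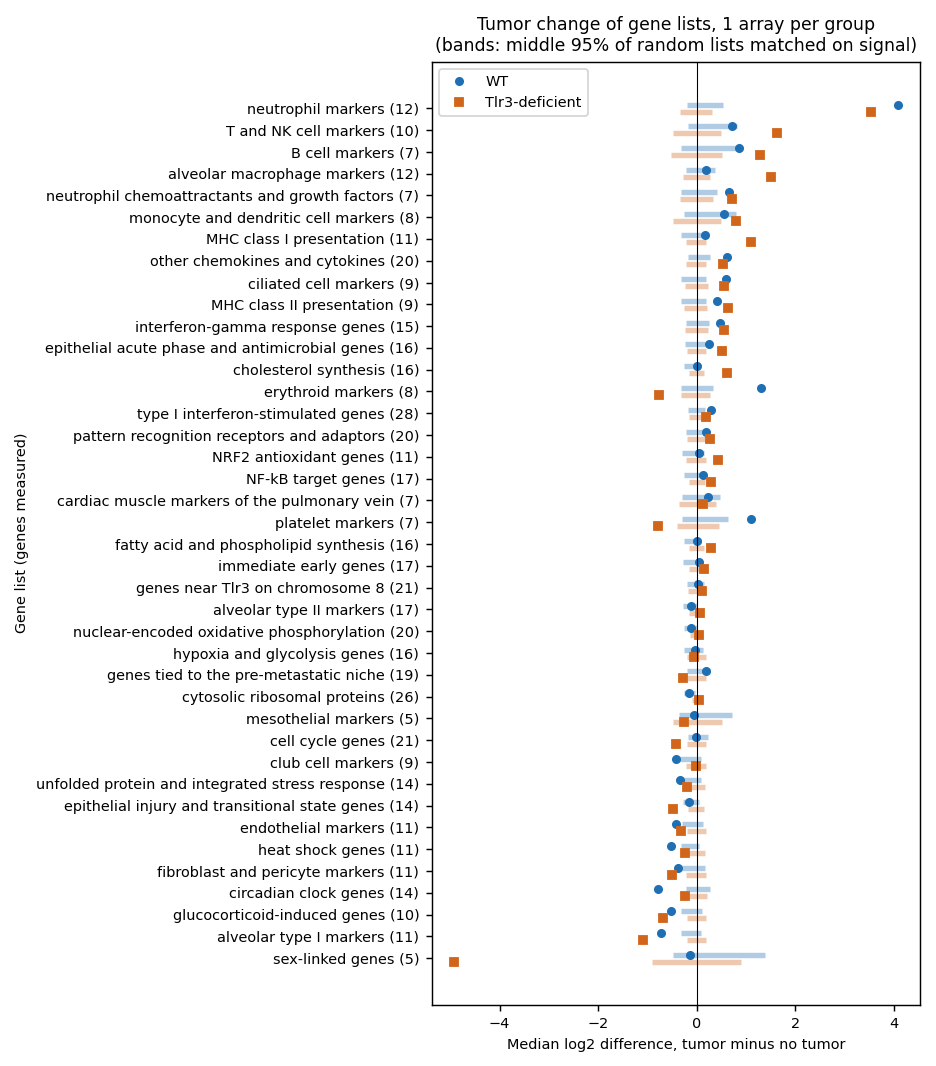
Median log2 difference with tumor (horizontal axis) of each gene list (vertical axis, genes measured in brackets) in WT (circles) and Tlr3-deficient cells (squares), with bands for the middle of random lists matched on signal. Neutrophil markers sit farthest right, at 4.09 and 3.54, and the sex-linked list farthest left in Tlr3-deficient cells, at -4.92 (7.85 where only Xist is left).

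Both tumor comparisons, which share no array but each set arrays of different slides against each other, had genes in common. Of 16960 genes tested in both, 256 were at least 2-fold higher in both and 66 lower in both, against 35.4 and 5.4 for independent lists, and 50 went opposite ways. With normexp 71 and 25 were shared, and without a filter 483 and 182. Highest in both were S100a8, Ifitm6, Wfdc17, S100a9, Clec4e, Mefv, Cd300lf, Retnlg, Il1r2 and Pirb. Genes lower in both included Rtkn2 (-1.55 in WT and -1.82 in Tlr3-deficient cells), a type I cell marker, Fbln5 (-1.44 and -2.07), an elastic fiber protein, Fras1, Sphk1, Ciart, Pxdc1, Cped1, Adamtsl2, Npr3 and Fam107a. With normexp Fbln5 (-0.80), Cped1 (-0.85) and Adamtsl2 (-0.69) were under 2-fold in WT and Ciart (-0.74) in Tlr3-deficient cells, and with the mean of its probes Fbln5 differed by -0.93 in WT, under 2-fold, and by -1.23 in Tlr3-deficient cells. Across the 15676 genes well above background on all 4 arrays, the tumor differences correlated at r = 0.381 (rho = 0.326), where genes are not independent replicates. Among genes in columns 52 to 85, 0.19% were lower in both, against 0.39% of all.

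**Figure D3:**
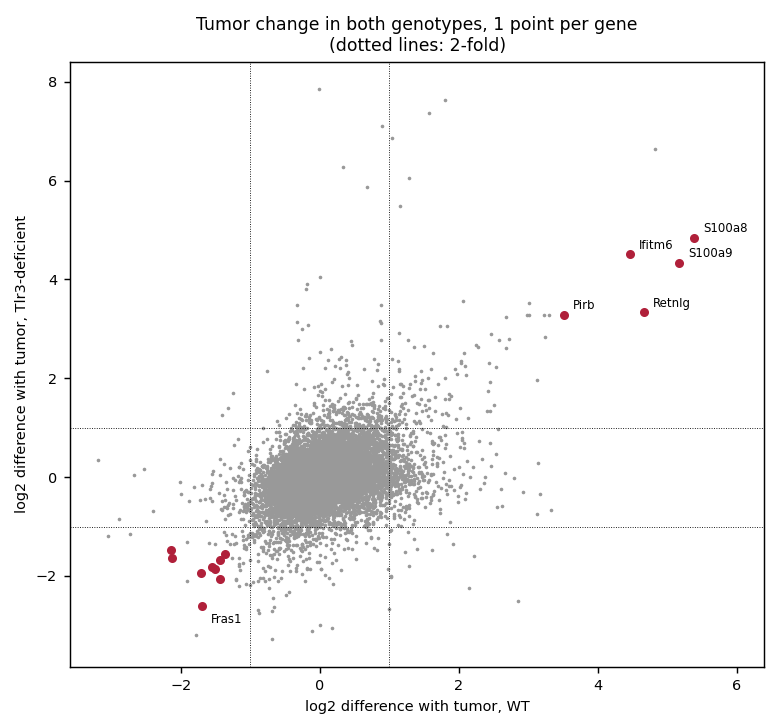
Log2 difference with tumor in WT (horizontal axis) against that in Tlr3-deficient cells (vertical axis), 1 point per gene well above background on all 4 arrays, with genes named as shared by both comparisons in red and dotted lines at 2-fold. S100a8 and S100a9 lie at the far right, at 5.39 and 5.17 in WT.

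Between genotypes with tumor, neutrophil markers were lower in Tlr3-deficient cells, with a median of -0.61 (percentile 0.05), although 1 of 12 was called lower (Ltf) and 1 higher (Mpo). Cxcl5 was 5.13-fold lower, Cxcl12 2.04-fold higher, and Cxcl1 (-0.35), Cxcl2 (-0.22), Cxcl3 (0.08), Csf2 (0.28) and Il1b (-0.15) were under 2-fold. The value table gives -8.34 for Cxcl1, -8.91 for Cxcl12 and -4.20 for Cxcl2 in this comparison, so for Cxcl12 the 2 sources differ in direction. The antimicrobial lectin Reg3g was 22.9-fold lower, and it was lower without tumor too (-1.93 log2). The largest differences of other ranked genes were those of Abra (-6.72), Fanca (-4.35), Rrp7a (-4.33), Fam89a (-3.69), Arxes1 (-3.68), Rbm45 (-3.34), Snhg18 (-3.28), Ooep (-3.26) and Rbp7 (-3.21) on the lower side. With the mean of all probes Fanca differed by -2.19, Rrp7a by -2.37 and Rbp7 by -2.38. On the higher side they were the antibody variable genes Igkv4-59 (5.68), Igkv4-55 (5.08) and Ighv1-77 (4.96), which were 3.97, 3.74 and 3.50 with normexp, followed by Psca (4.72), Jchain (4.52), Slc6a20a (4.29), the fibrinogen chain Fgg (4.08), Cyp26b1 (3.57) and Iglv1 (3.39). Igkv1-117 was at least 76.5-fold higher by its brightest probe, which was not well above background on the WT tumor array, and differed by 4.14 at its other probe, by 6.23 with the mean of both and by 4.55 with normexp. Igkv3-4, Igkv4-57-1 and Igkv4-86 were at least 96.4-, 20.9- and 13.7-fold higher (4.61, 2.87 and 1.96 log2 with normexp). Prg2 was at least 18.1-fold and Catspere1 at least 9.87-fold higher, and Raet1e was at least 20.04-fold lower, with Raet1a, Adamtsl3, Apol7a and Grap2 at least 8.09-, 7.88-, 7.77- and 7.13-fold lower by their brightest probes. With the mean of all probes Adamtsl3, Apol7a and Grap2 differed by -2.17, -2.19 and -1.72 log2, less than those bounds.

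With tumor, Tlr3-deficient cells had higher medians for MHC class I (0.64; 2 of 11 called), alveolar macrophage markers (0.49), endothelial markers (0.47), MHC class II (0.37), type I markers (0.34), interferon-gamma response genes (0.25), acute phase genes (0.25), the unfolded protein response (0.25) and other chemokines (0.20). Erythroid markers (-1.35; 7 of 8 lower), glucocorticoid-induced genes (-0.39), ciliated (-0.36) and club cell markers (-0.24) were lower. In all, 528 genes were higher (205 as bounds) and 478 lower (188 as bounds) of 18105, against 245 and 183 with normexp and 1042 and 1262 without a filter.

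Without tumor, Agpat4 (3.65) and Pttg1 (3.16) were higher in the array labelled Tlr3-deficient, no tumor, and Abra (-4.89), Fanca (-3.45, but -1.56 with the mean of all probes) and Fam89a (-3.43) lower, each in the direction seen with tumor. Lypd6 and Racgap1 were at least 3.85-fold and 3.75-fold higher by their brightest probes, which were not well above background on the WT array without tumor, but their other probes differed by -0.06 and -0.23, and the differences were 1.75 and 1.65 with the mean of all probes and 0.59 and 0.68 with normexp. Gp9, a platelet glycoprotein, was 8.60-fold higher. Psca was at least 28.2-fold and Rasgrf2 at least 8.199-fold higher, and Cthrc1 and Raet1e at least 18.0- and 13.9-fold lower, with Hykk, Spag6 and Vmn2r59 at least 8.64-, 6.76- and 6.07-fold lower by their brightest probes. With the mean of all probes Cthrc1, Hykk and Spag6 differed by -2.84, -3.05 and -2.13 log2, less than those bounds. Platelet markers (median 2.16; 6 of 7 higher), mesothelial (0.87), fibroblast (0.76), erythroid (0.71), type I (0.61), endothelial markers (0.43), interferon-gamma response (0.39), niche (0.33), transitional state (0.30), type I interferon-stimulated (0.18, but -0.06 with normexp) and unfolded protein response genes (0.09, but -0.01 with median centring) stood apart upward. Cholesterol synthesis (-0.65), club cell markers (-0.64), T and NK cell markers (-0.49), macrophage markers (-0.47), NRF2 genes (-0.42), ciliated markers (-0.40), genes near Tlr3 on chromosome 8 (-0.33) and clock genes (-0.30) stood apart downward. In this comparison 1032 genes were higher (418 as bounds) and 409 lower (146 as bounds) of 17428, against 501 and 237 with normexp. Without a filter they were 2101 and 1020, and the value table gave 623 lower. Among genes in columns 52 to 85, however, 2.09% were higher and 2.93% lower, against 5.92% and 2.35% of all. In columns 1 to 51, where the WT array without tumor scattered more, 8.46% were higher and 1.99% lower. The excess of higher genes lay there, as did all 5 of the largest measured higher genes named.

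Of 16852 genes tested in both genotype comparisons, which share no array, 98 were higher in both and 100 lower in both, against 16.5 and 7.0 for independent lists, and 57 went opposite ways. With normexp 44 and 62 were shared, and without a filter 242 and 236. Across genes well above background on all 4 arrays the genotype differences correlated at r = 0.300 (rho = 0.204).

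The difference of tumor changes between genotypes addresses whether the tumor response depends on Tlr3. The tumor change was at least 2-fold higher in Tlr3-deficient cells for 332 and lower for 706 of 15676, but with median centring the counts were 494 and 502, so that 49.6% and not 32.0% of them were higher. Without a filter they were 1491 and 2858, and with normexp 218 were higher. Among the ranked genes, higher were Iglv1 (6.21), Jchain (5.80), Cd5l (3.54), Igkv4-72 (3.26), Fgg (3.09) and the airway protein Bpifa1 (2.95), besides Xist and Tsix. Lower were Rec114 (-4.39), Rbp7 (-4.00), Kntc1 (-3.65), Slc4a1 (-3.51), Gp9 (-3.28), the antiviral gene Rsad2 (-3.23) and Fbn2 (-3.22), with Rec114 at -2.33 and Rbp7 at -3.09 with the mean of all probes. Sstr4 ranked ahead of them (-5.37), but its brightest probe was not well above background on the WT array without tumor, and its other probe read -4.77 and -4.68 in WT and -4.03 and -4.12 in Tlr3-deficient cells. Macrophage markers (0.92), MHC class I (0.71), cholesterol synthesis (0.51), NRF2 genes (0.50), acute phase genes (0.47), T and NK cell markers (0.43 with 5 of 10 below 0, but -0.05 with only genes well above background on all 4 arrays), club cell markers (0.39), MHC class II (0.38) and clock genes (0.25, but -0.08 with the mean of all probes) stood apart upward. Erythroid (-2.21) and platelet markers (-1.99), fibroblast markers (-0.76), glucocorticoid-induced genes (-0.63), niche (-0.59), cell cycle (-0.44), type I interferon-stimulated (-0.26), type I (-0.23), transitional state (-0.23) and sex-linked genes (-6.69, but 7.86 where only Xist is left) stood apart downward, 10 lists against 6 with normexp. Neutrophil markers (-0.44) and neutrophil attractants (0.05) did not stand apart. These list medians, unlike the counts, can include members not well above background on all 4 arrays, at measured values. The difference rests on all 4 arrays, the noisier WT array and the array with Y-linked transcripts among them, and in columns 52 to 85 2.98% of genes were lower, against 4.50% of all.

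The remaining lists lay within the range of random lists in all 5 comparisons: alveolar type II markers, ribosomal proteins (medians -0.15 in WT and 0.05 in Tlr3-deficient cells with tumor), oxidative phosphorylation (-0.12 and 0.05), hypoxia and glycolysis genes (-0.04 and -0.05) and cardiac muscle markers of the pulmonary vein (0.24 and 0.12).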

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

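The other-sex test and 2 of the 3 tests on neutrophil genes were set before their results were seen; the tests of a wrong genotype label, an exchange of labels, a lower share of type II cells and all tests on shared genotype differences were chosen after the results were seen.

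The tumor difference of erythroid markers was 1.30 in WT and -0.77 in Tlr3-deficient cells, and that of platelet markers 1.10 and -0.79. They drew attention because the 2 genotypes went opposite ways; the difference was not tested, since each group is 1 array. Between genotypes platelet markers differed by 2.16 without and 0.14 with tumor, and erythroid markers by 0.71 and -1.35. The WT tumor array and the array with Y-linked transcripts, which share a slide, were the ones with the higher medians of these markers in the tumor comparisons.

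The array labelled Tlr3-deficient, no tumor, carried Y-linked transcripts and little Xist although all mice are labelled female. A wrong genotype label is argued against, since 51.3% of the 76 genes at least 4-fold different between genotypes with tumor were at least 2-fold different the same way without tumor and 9.2% the opposite way. Genes that escape X inactivation came from a list written before they were looked at. They were lower in this array than in WT without tumor (median -0.49) and than in Tlr3-deficient with tumor (median -0.32), 5 of 5 in each. This goes with RNA from an animal of the other sex than labelled. Against WT without tumor, however, Ddx3x (-0.03) and Pbdc1 (-0.25) lay within the replicate-spot SD of 0.293, and Ddx3x differed by 0.70 with tumor in WT. An exchange of labels within the series would not account for Y-linked transcripts, since all 4 arrays are labelled female. One with a WT array is also argued against by the genes within 10 Mb of Tlr3. Of these, 8 differed between genotypes the same way without and with tumor, 0 in opposite ways, and 1 was shared by both tumor comparisons. Random draws, made for the first of these counts alone, mostly gave 3 or fewer. Whether that animal was mislabelled or exchanged with one from outside the series stays open, as does any sex difference among the genes called.

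Neutrophil transcripts were higher with tumor in both genotypes. A lower share of type II cells, filled by every other type alike, would raise the markers of all of them. Endothelial markers were instead lower (median -0.42 in WT), as were type I and fibroblast markers in both genotypes, which argues against that form. A share lost to neutrophils or other blood cells alone would lower these markers too, so the test cannot decide on that. S100a8 and S100a9 made by the epithelial cells alone would leave other neutrophil genes where they were. A median over 2-fold in both genotypes, for further neutrophil genes from a list written beforehand, was set as evidence against it. The measured medians were 2.32 in WT and 2.30 in Tlr3-deficient cells, past that limit. With 7 and 9 members at their bound they were 1.27 and 0.95 log2, the latter under 2-fold. With bounds the test therefore does not decide. Some of the listed genes, such as Itgam and Cybb, are also expressed by monocytes and macrophages. Monocyte and macrophage markers had tumor medians of 0.80 and 1.51 in Tlr3-deficient cells, and 0.56 and 0.18 in WT. The list cannot tell neutrophil RNA from that of other myeloid cells, so it does not decide on the source of S100a8 and S100a9. Neutrophil RNA in the sorted cells may account for the pattern, with the abundant S100a9 at 6.31 log2 units over the 75th percentile on the WT tumor array. Of further neutrophil genes, 44.4% (8 of 18) were at least 2-fold higher in both genotypes. This lies between the bounds set beforehand for and against neutrophil RNA, so it stays open. How far the sort removed other cells was not measured. Transcripts of red cells (Slc4a1) and plasma cells (Jchain) were also well above background on every array. A change of neutrophil-type genes within the type II cells, from the tumor, is also open and untested.

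Genes differed between genotypes in the same direction without and with tumor. Spot noise of the WT array without tumor is argued against as the cause, since the comparisons share no array and the shared number was 5.93 (higher) and 14.3 (lower) times that of independent lists. Independent lists can be a low mark, if genes that vary more are called more often in either direction. The 98 and 100 genes shared each way still exceeded the 57 that went opposite ways. Alleles linked to the targeted locus could account for genes near it, since 8 of 63 genes within 10 Mb of Tlr3 were shared against a random median of 1, which puts it at the top of the random draws, but not for all, since 7.7% of 182 shared autosomal genes lay on chromosome 8. Further chromosome segments that differ between the mouse lines are a candidate explanation for others: the fullest 20 Mb window outside chromosome 8 (chromosome 9, 40 to 60 Mb) held 12 shared genes of 215, against a random median of 7 (percentile 99.82). An effect of Tlr3 loss itself and a difference between slides stay open and were not tested.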

How the results depend on the processing

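The column split, lists with every gene at its bound, the counts without chromosomes X and Y and those with the background flag of the representing probe alone were chosen after the data were seen; the other alternatives were planned. No paired analysis was possible because each group is 1 array with no shared replicate numbers to pair, and slide as a block was not run because no residual degrees of freedom remain. Of the counts of genes under the alternatives fixed beforehand, 89 lay within 1.5 times the main count and 37 did not. Of the counts of lists that stood apart, 89 did and 1 did not, but which lists these were changed more. For tumor in WT, 10 of 14 upward and 6 of 8 downward lists kept their call with normexp. With quantile normalization 13 and 8 did. For tumor in Tlr3-deficient cells 15 of 19 upward lists kept it with the mean of all probes. Between genotypes without tumor 9 of 12 upward lists did with normexp. Of differences of named genes, 895 moved by less than the larger of the replicate-spot SD and the scanner's error and 173 by more. Of list medians, 1229 moved by less than the spread that spot noise gives a median, 559 by more, and 12 changed sign, among those that stood apart. A filter changes how many genes are tested, no filter lets genes near background in, and the normexp offset of 50 shrinks differences of dim genes. For other changes the cause was not tested.

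With normexp, which shrinks differences of dim genes, the higher and lower counts were 460 and 126 for tumor in WT, 405 and 327 for tumor in Tlr3-deficient cells, 501 and 237 between genotypes without tumor, and 245 and 183 with tumor; 218 tumor changes were higher in Tlr3-deficient cells, 71 and 25 genes were shared by both tumor comparisons, 44 and 62 by both genotype comparisons, and 6 lists stood apart downward for the difference of tumor changes against 10. With only genes well above background on all 4 arrays the counts were 544 and 147, 440 and 359, 596 and 256, and 229 and 237, with 130 shared higher with tumor. With no filter they were 2072 and 812, 1443 and 1567, 2101 and 1020, and 1042 and 1262, with 1491 and 2858 differences of tumor changes, 483 and 182 shared tumor differences and 242 and 236 shared genotype differences. The value table gave 623 genes lower between genotypes without tumor.

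The correlation of tumor differences was 0.332 with normexp and 0.232 without a filter, and that of genotype differences 0.107 without a filter and 0.257 with the mean of all probes. In columns 52 to 85 the shares were 3.40% (higher with tumor in WT), 2.52% (lower with tumor in Tlr3-deficient cells) and 2.09% (higher between genotypes without tumor, where 2.93% were lower). They were 2.98% (lower tumor change in Tlr3-deficient cells) and 0.19% (lower in both) for the others. Without chromosomes X and Y no share moved by over 1.5 times, and with the flag of the representing probe alone none of 14 counts did (1004 and 276 for tumor in WT). Tlr3 differed by 0.36 with tumor in WT with the mean of its probes and by 7.44 in the value table, by -0.61 between genotypes without tumor with normexp and -1.03 in the table, and by -0.62 with tumor with normexp and -8.25 in the table.

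List medians that changed sign were those of T and NK markers for the difference of tumor changes (-0.05) and sex-linked genes (7.85 with tumor in Tlr3-deficient cells, -8.10 between genotypes without tumor, 7.86 for the difference of tumor changes) with only genes well above background on all 4 arrays, which leaves Xist alone; with normexp, interferon-stimulated genes (-0.06) and the unfolded protein response (-0.07) between genotypes without tumor and MHC class I with tumor in WT (-0.09); with median centring, NF-kB targets (-0.02) and immediate early genes (-0.10) with tumor in WT and the unfolded protein response between genotypes without tumor (-0.01); and with the mean of all probes, immediate early genes with tumor in WT (-0.01) and clock genes for the difference of tumor changes (-0.08). Calls higher made up 78.4% for tumor in WT, 66.4% with quantile normalization and 63.7% with median centring, and for the difference of tumor changes 32.0% against 49.6% with median centring. The median of all genes was -0.03 for tumor in WT and -0.06 between genotypes without tumor, against -0.18 and -0.16 with median centring and -0.13 and -0.16 with normexp. Signal over background limits 427 of the 1007 higher WT tumor calls to a bound.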

Other observations

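The count of antibody genes and the probe comparison below were chosen after their values were seen.

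Antibody genes separated the Tlr3-deficient tumor array from the others. Of the 22 genes on the array design named for antibody heavy or light chains, 20 were well above background on that array, 9 of them there alone, against 11 on the WT tumor array, 8 on the WT array without tumor and 5 on the array labelled Tlr3-deficient, no tumor. With tumor, 19 were at least 2-fold higher in Tlr3-deficient cells against 5 in WT, and 17 were higher in Tlr3-deficient than in WT cells. In WT 1 was lower with tumor (Igkv1-117, by a probe not well above background with tumor). Its other probe went the opposite way in WT, from -7.24 without tumor, not well above background, to -4.83 with tumor. Without tumor, 3 were lower in the array labelled Tlr3-deficient than in WT, Iglv1 7.05-fold, Igh-VJ558 3.28-fold and Igkv4-59 at least 2.14-fold, so the tumor difference in Tlr3-deficient cells starts from a lower value for these genes. Igh-VJ558 was 117-fold higher with tumor in Tlr3-deficient cells, while Ighm, the heavy chain of B cells before class switching, was 3.21-fold higher in Tlr3-deficient and 3.62-fold in WT cells. These genes resemble each other, so probes can share signal, and they are not independent measurements. The polymeric antibody receptor Pigr, which carries J-chain-bound antibody across epithelia, was 8.29-fold higher with tumor in Tlr3-deficient and 3.55-fold in WT cells.

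The series' value table and the scanner files gave different values at 6 probes. Across 41174 probes, after the smooth level-dependent difference between both was removed, the table lay within 0.24 log2 units of quantile-normalized scanner values except at all 6 probes of Tlr3 (2 probes), Cxcl1, Cxcl2 and Cxcl12 (2 probes). Of their 24 values, 21 differed by over 0.5, and 19 of these lay within 0.1 of a whole log2 number, such as -10, -9 and -8 for Cxcl1 on the arrays other than WT tumor. All 3 differing values on the WT tumor array were higher in the table (Tlr3 by about 4 and 5, Cxcl12 by about 3), and all 18 on the other 3 arrays were lower. Of all other table values, 99.6% exactly equalled a value in another column, as quantile normalization leaves them, and so did the 3 values of these probes that did not differ, against 0 of the 21. In the scanner files these spots lay at -0.37 to 0.40 from the array's trend of processed on mean signal, within the range that holds nearly all probes (-0.62 to 1.0), and the 8 probes of other neutrophil attractants differed by at most 0.01. How the differing values arose was not tested, and nothing in the sources used here describes a step that makes them. Read from the table, these genes give WT tumor differences of 10.25 (Cxcl1), 7.44 (Tlr3), 7.24 (Cxcl12) and 3.89 (Cxcl2), and read from the scanner files 0.13, -0.02, 0.20 and 0.97.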
